A study of Mus musculus with 12 samples.

How the data were processed

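The samples were CD4 T cells from mouse spleen, 3 arrays for each of 4 groups: Cre- and Cre+ cells at baseline, and both genotypes after 24 hours with plate-bound antibody to CD3 and soluble antibody to CD28. Total RNA was labelled with biotin and hybridised to whole-transcript arrays with 1 value per gene. The deposited values are log2 expression, made by the authors with RMA, affy 1.36.1 and R 2.15.1 as the labels name them, and the unit was checked on the values, which ran from 0.542 to 13.2. The chip definition file and the genome build are not given in the sources used here, so no coordinates are reported. The number of arrays limits the precision. No source used here states that the replicates were separate animals, so a p-value measures the spread between samples. The expression of Xist and Eif2s3y showed both sexes within every group, so each group held arrays from more than 1 animal. Whether all 3 arrays of a group came from separate animals stays open.

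The table held 25206 probe sets. Each of 23185 paired with exactly 1 gene through its gene identifier, and these were tested. The other 2021 had no gene listed and were left out of the comparisons. Groups were taken from the labels of genotype and state. The 5 comparisons were Cre+ against Cre- at baseline, Cre+ against Cre- after activation, activation in each genotype, and the difference of the activation responses. One limma model (limma 3.58.1, R 4.3.3) with a mean per group was fitted to all 12 arrays without covariates, with 8 residual and 3.55 prior degrees of freedom, and a gene passed at a two-sided Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no fold minimum. The standard errors (SE) are the moderated ones of this model, and the SD values are taken over the 3 arrays of a group.

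Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 33 lists of a comparison. Of 428 distinct genes on the lists, 395 were measured, and some genes were on several lists. The lists covered the Ikaros family, naive and quiescence genes, activation markers, Th1, Th2, Th17, regulatory and follicular helper T cell genes, cytotoxic genes, cytokines, interferon-stimulated genes, the Notch pathway, the IL-2 and STAT5 pathway, T cell receptor signalling, inhibitory receptors and anergy genes, chemokine receptors and integrins, the NuRD and Sin3 complexes, cell cycle, glycolysis, cholesterol synthesis, ribosome biogenesis, the unfolded protein response, p53 targets, immediate early and stress genes, immature thymocyte genes, markers of CD8 T cells, B cells, myeloid cells, NK cells, gamma delta and innate-like T cells, erythroid cells and platelets, and genes linked to sex.

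The named genes were Ikzf1, the 12 largest increases and 12 largest decreases that passed in a genotype comparison, 8 of each in an activation comparison and up to 10 of each for the difference of responses, where in the first 4 comparisons the 3 values of one group all lay above those of the other. Unnamed or predicted genes, pseudogenes and rearranging receptor segments were left out of these ranks. Each list added up to 4 members that passed with the smallest adjusted p, or the 2 with the smallest p where fewer than 2 passed. The cytokine genes Il2, Ifng, Csf2, Il17a, Il22 and Il10, the factors Tbx21, Gata3 and Foxp3, and the markers of other cell types could be named at any value. The model, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise.

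The alternatives were the replicate number as a block, a variance trend with robust moderation, array weights, means of at least 5 or 6 over all arrays, all 25206 probe sets, median centring, quantile normalization, arrays set to their 75th percentile, a 2-fold minimum, only the arrays compared, an estimated correlation for lists, and each array left out in turn. After seeing the data, 2 more were added: a fit without the third activated array of both genotypes, and sex as a covariate. The model was tested on simulated data with 23185 genes, where it recovered 85% of genes planted at 2-fold and 96% of those planted at 4-fold, with 12 false calls. The simulation planted changes in the Cre+ baseline group only. Its noise was independent between genes and arrays, with the same SD for a gene in every group. It therefore does not cover the wider spread of the activated arrays or the comparisons that use them.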

Results

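The series measured gene expression in CD4 T cells from mouse spleen on 12 whole-transcript arrays. Ikaros, the zinc finger transcription factor encoded by Ikzf1, was deleted with a Cre recombinase driven by the T lineage promoter of Lck. Cre- cells carried intact Ikaros, and Cre+ cells were labelled as lacking it. Cells of each genotype were taken at baseline, labelled 0 hours, or activated for 24 hours through CD3 and CD28. These are the T cell receptor complex and its main costimulatory receptor. Each of the 4 groups held 3 arrays. The comparisons asked how expression differed between Cre+ and Cre- cells at rest and after activation. They also asked what activation did in each genotype and whether the activation responses differed. No group carried Cre with intact Ikaros, so an effect of Cre itself cannot be told apart from that of Ikaros loss. No group was cultured for 24 hours without antibodies to CD3 and CD28. An effect of culture therefore cannot be told apart from that of activation. Values are log2 expression, and 23185 genes were tested. Array medians lay between 4.04 and 4.17, and the number of arrays per group limited the precision. Whether dim genes lay above background was not tested, so a fold against a group that read below the array medians compares readings, not amounts of transcript. Arrays of the same group correlated across genes at 0.992 to 0.993 at baseline. The activated arrays spread more, with correlations of 0.9715 to 0.9937 in Cre- cells and 0.9763 to 0.9899 in Cre+ cells.

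Ikzf1 itself was measured first. Its probe set read 10.53 ± 0.01 (SD, n = 3) in Cre- and 10.36 ± 0.27 in Cre+ cells at baseline, a log2 difference of -0.17 (SE 0.13, limma adjusted p = 0.968), which was -0.32 without Cre+ baseline array 1 and -0.06 without Cre+ baseline array 3. After activation it read 10.11 ± 0.10 in Cre- and 9.98 ± 0.13 in Cre+ cells, a difference of -0.13 (SE 0.13, limma adjusted p = 0.993), which was -0.20 without Cre+ activated array 1, -0.07 without Cre- activated array 2 and -0.08 without Cre+ activated array 3 or with array weights. The deleted exons are not given in the sources used here, and the single value per gene can include undeleted parts of the transcript. The Ikzf1 level therefore did not check the genotype labels, and the groups are named as labelled. Among the relatives of Ikaros at baseline, Ikzf3 (Aiolos) stood 0.73 higher in Cre+ cells (SE 0.26) and Ikzf4 (Eos) 0.86 higher (SE 0.35), and neither passed in the fit of all arrays (limma adjusted p = 0.503 and 0.618). Both passed in the fit of the 6 baseline arrays alone (limma adjusted p = 0.0129 each) and in the fit without the activated arrays numbered 3 (0.00651 and 0.0158), so these calls depend on the arrays in the fit. None of the 5 measured family members passed in either state with all arrays.

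At baseline, Slc43a1, an amino acid transporter gene, rose in Cre+ cells from 4.62 ± 0.18 to 7.87 ± 0.05 (SD, n = 3), a 9.51-fold difference. Tmem204 rose by 3.03 and the zinc finger gene Zfp704 by 2.85 on the log2 scale, from Cre- readings of 3.60 and 3.58, below the array medians. Itgam, which encodes the integrin CD11b and was fixed as a myeloid marker, rose 6.62-fold, from 5.77 ± 0.42 to 8.49 ± 0.23. Dapl1 fell by 1.81 on the log2 scale and Prf1, which encodes the pore-forming protein perforin, fell by 1.53.

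The increases continued with Eng, the TGF-beta co-receptor endoglin (log2 fold change 2.28), the peptide transporter gene Slc15a1 (2.21) and Ctnnd1, which encodes p120 catenin (2.09, SE 0.19, limma adjusted p = 0.000384). Cd163l1 rose by 2.08, Ifitm3, an interferon-induced membrane protein gene, by 2.00, Lxn by 1.97, Adgrg3 by 1.95 and Trim16 by 1.91. Decreases were fewer and smaller. After Dapl1 and Prf1 came Cpm, which encodes a carboxypeptidase, with a fall of 1.13, then Raver2 (-0.86), Padi2 (-0.83), Armcx2 (-0.74), Klhdc2 (-0.70), Rgs11 (-0.68), Tpbgl (-0.66), Ccdc30 (-0.56) and Chpt1 (-0.50). Of these decreases Prf1 and Raver2 kept their calls in every setting that tested them, while Dapl1 and Cpm lost theirs in 4 settings each, Armcx2 in 6, Padi2 in 8, Tpbgl in 9, Rgs11 in 12, Klhdc2 and Chpt1 in 15 each and Ccdc30 in 16. Of the increases named, Ifitm3 lost its call in 7. In total 128 genes passed the limma test at baseline, 114 higher and 14 lower in Cre+ cells. At least 2-fold changes were seen in 61 of them, 56 higher and 5 lower.

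Interferon-stimulated genes were shifted upward in resting Cre+ cells. Of 29 measured members, 2 rose, Oas2 by 1.83 (SE 0.22, limma adjusted p = 0.00209) and Ifih1, a sensor of viral RNA, by 1.10, a call lost in 6 alternative settings. Adjusted over the list alone, 10 members rose and none fell. The list's median was 0.43 (camera adjusted p = 3.9e-14, and adjusted p = 0.093 with an estimated correlation). The 18 activation markers had a median of 0.27 (camera adjusted p = 0.00020, and adjusted p = 0.049 with an estimated correlation). Among them Irf4, a transcription factor induced by receptor signals, rose from 6.52 ± 0.09 to 7.48 ± 0.16, and Il2ra read 0.48 higher without passing. Adjusted over the list alone, 5 activation markers rose.

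Among 18 regulatory T cell genes, Nrp1 rose by 0.66, a call lost in 12 alternative settings, and the others did not pass, with 3 higher when adjusted over the list alone. The list's median was 0.31 (camera adjusted p = 0.00149, and adjusted p = 0.678 with an estimated correlation). Foxp3, the lineage factor of regulatory T cells, differed by 0.17 (SE 0.33). The IL-2 and STAT5 pathway had a median of 0.31 with no member passing (camera adjusted p = 0.00259, and adjusted p = 0.437 with an estimated correlation). Cholesterol synthesis genes had a median of -0.17 with no member passing (camera adjusted p = 0.047, and adjusted p = 0.817 with an estimated correlation). In the cytotoxic list Prf1 fell while Serpinb6b, a serine protease inhibitor gene, rose by 1.33. Sox13, a marker of gamma delta T cells, rose by 0.92, and the other 3 measured markers of that list did not pass. None of 24 cytokine genes passed at baseline, with 2 higher when adjusted over the list alone and 2 higher in the fit without the activated arrays numbered 3. At baseline Il2 read 2.70 in Cre- and 2.83 in Cre+ cells and Ifng read 3.66 and 3.65.

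No list of markers of another cell type passed at baseline in the fit of all arrays. The median of 14 B cell markers was -0.18 (camera adjusted p = 0.057, and 0.00982 in the fit without the activated arrays numbered 3), and that of 14 myeloid markers was -0.06, with Itgam the only member to pass. Genes linked to sex showed 1 female array of 3 in the Cre- and 2 of 3 in the Cre+ baseline group. With sex as a covariate, chosen after seeing the data, 85 genes passed, while a fit of the 6 baseline arrays alone called 251, array weights 321, and a fit without the activated arrays numbered 3, also chosen after seeing the data, 266. Leaving out 1 baseline array gave 60, 54 and 60 genes without Cre- arrays 1, 2 and 3, and 50, 51 and 54 without Cre+ arrays 1, 2 and 3, and leaving out Cre- activated array 3 gave 199.

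**Figure D1:**
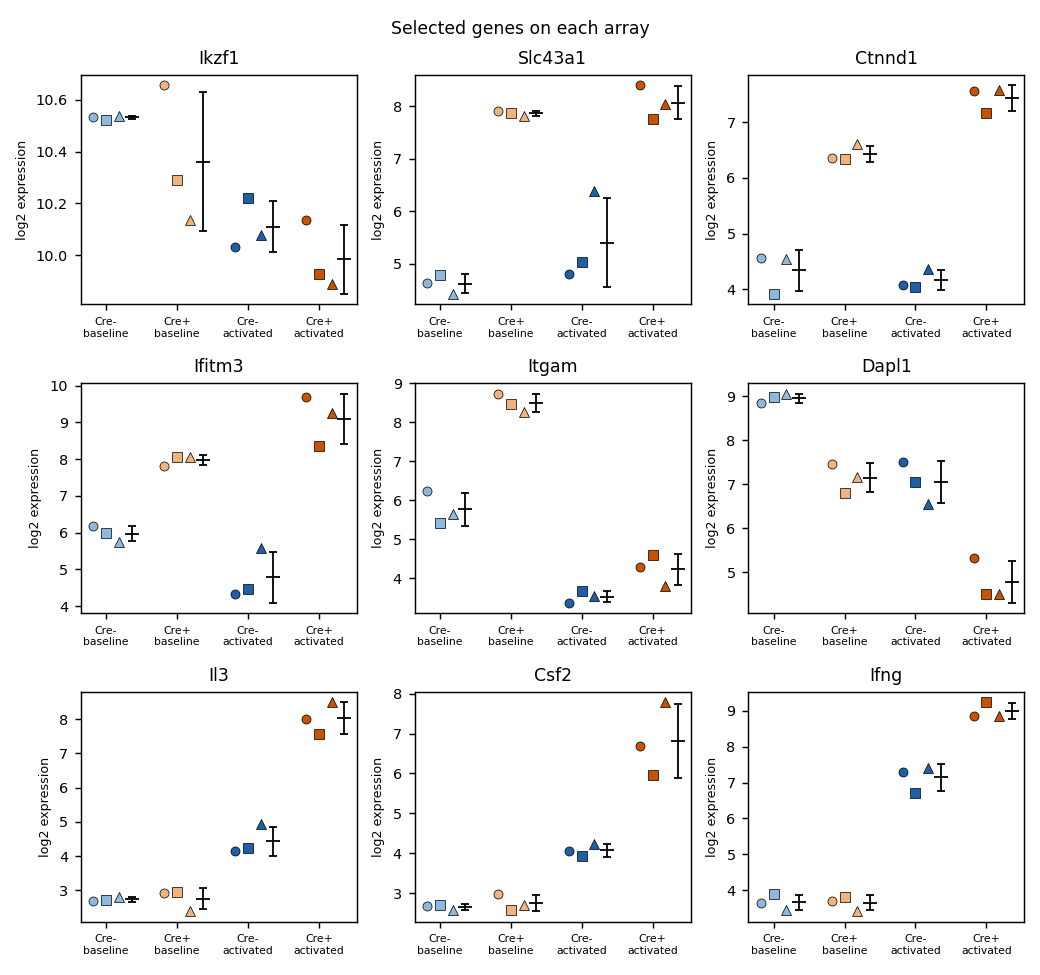
Log2 expression of 9 genes on each of the 12 arrays. Circles, squares and triangles are the arrays numbered 1, 2 and 3 of each group, bars are the mean and SD of 3 arrays, and Slc43a1 and Ctnnd1 were higher in Cre+ cells in both states, Itgam at baseline, and Il3, Csf2 and Ifng after activation.

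After activation, Cre+ cells expressed more of several cytokine genes than Cre- cells. Il3, which encodes a haematopoietic growth factor, read 8.03 ± 0.46 (SD, n = 3) in Cre+ and 4.44 ± 0.43 in Cre- cells, a 12.1-fold difference (SE 0.25 on the log2 scale, limma adjusted p = 6.2e-05). Csf2, which encodes GM-CSF, was 6.68-fold higher at 6.81 ± 0.92 against 4.07 ± 0.16. Ifng was 3.59-fold higher at 8.99 ± 0.22 against 7.14 ± 0.38. Tnfsf11, which encodes RANKL, was higher by 1.87 on the log2 scale, and Il2 by 1.49.

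Genes outside the cytokines differed as strongly. Ifitm3 was 19.8-fold higher in activated Cre+ cells (9.10 ± 0.68 against 4.79 ± 0.69) and Stra6, which encodes a retinol transporter, was 19.4-fold higher (8.83 ± 1.26 against 4.55 ± 0.90). Ctnnd1 was 9.63-fold higher (SE 0.19 on the log2 scale, limma adjusted p = 1.2e-05), followed by the growth factor gene Pdgfb (log2 fold change 2.68), Slc43a1 (2.67), Klrb1f (2.65), Tmem176b (2.54), Anxa1 (2.47, a call lost in 12 alternative settings), the receptor kinase gene Axl (2.38) and Ccn4 (2.36 at an SE of 0.13). Without Cre+ activated array 2 Stra6 was 32.1-fold higher, and without Cre+ activated array 3 the log2 fold change of Anxa1 was 1.70. Dapl1 was lower by the widest margin, at -2.27. Atp1b1, a sodium pump gene, read 6.57 in Cre+ and 7.57 in Cre- cells (SE 0.16, limma adjusted p = 0.0131). Further decreases were in Zfp273 (-1.01), Zcwpw1 (-0.99), Rtn4rl1 (-0.98), Sema4f (-0.88), Pkd1l3 (-0.87), Rhoh (-0.85), Chst10 (-0.84), Dhcr7 (-0.80), Padi2 (-0.79) and Bphl (-0.75). Each of these decreases lost its call in at least 1 alternative setting, Dapl1 in 1, Zcwpw1, Pkd1l3 and Bphl in 2 each, Rtn4rl1 in 3, Zfp273 and Atp1b1 in 4 each, Dhcr7 in 6, Rhoh, Chst10 and Padi2 in 10 each and Sema4f in 11. Of the increases, Ifitm3, Stra6, Pdgfb, Slc43a1, Klrb1f, Tmem176b and Axl each lost their call in 1 setting, the fit of the activated arrays alone. In total 169 genes passed the limma test, 146 higher and 23 lower, and 95 of them changed at least 2-fold, 92 higher and 3 lower.

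Of 24 cytokine genes, 5 were higher in activated Cre+ cells (Il3, Csf2, Ifng, Tnfsf11 and Il2) and none was lower, and 10 were higher when adjusted over the list alone. The cytokine median was 0.50 (camera adjusted p = 4.0e-14), and this list kept its call with an estimated correlation (adjusted p = 0.00491). In the fit of the 6 activated arrays alone Il3 kept its call, while Csf2 (adjusted p = 0.157), Ifng (0.0937), Tnfsf11 (0.0838) and Il2 (0.440) lost theirs, and Il2 lost its call in 13 settings. Il17a, Il22 and Il10 differed by 0.25, -0.14 and -0.32 and did not pass. The IL-2 and STAT5 pathway had 2 of 13 members higher, Il2 and Stat5a (0.60, a call lost in 7 settings), 3 when adjusted over the list alone (camera adjusted p = 0.00109, and adjusted p = 0.184 with an estimated correlation). Among 15 Th1 genes, Ifng passed alone, with 3 higher when adjusted over the list alone (camera adjusted p = 0.00213, and adjusted p = 0.205 with an estimated correlation), and Tbx21, the lineage factor of Th1 cells, differed by -0.01 (SE 0.14). Gata3, the Th2 factor, differed by -0.03 and Foxp3 by 0.23, and neither passed.

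Interferon-stimulated genes had 3 of 29 members higher after activation, Ifih1 (1.46), Oas2 (1.71) and Oasl2 (1.74), and 6 higher and 1 lower when adjusted over the list alone. None of the 3 passed in the fit of the activated arrays alone, and Oasl2 lost its call in 14 settings. Their median was 0.18 (camera adjusted p = 6.7e-06, and adjusted p = 0.205 with an estimated correlation). Immediate early and stress genes had a median of 0.30, with Ier3 higher by 2.24 and 5 members higher when adjusted over the list alone (camera adjusted p = 6.7e-06, and adjusted p = 0.184 with an estimated correlation). Cytotoxic genes had a median of 0.32 with no member passing, and 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00213, and adjusted p = 0.0912 with an estimated correlation). The 12 Th17 genes, 18 activation markers and 11 p53 targets also shifted upward without a member passing, at camera adjusted p = 0.0391, 0.0372 and 0.0276. With an estimated correlation their adjusted p = 0.184, 0.184 and 0.210. The estimated correlations of the Th17 genes (-0.0691), activation markers (-0.0126) and cytotoxic genes (-0.0246) lay below the preset 0.01. A higher correlation between members therefore does not account for the loss of those calls.

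Of the lists of markers of other cell types, those of B cells and myeloid cells passed upward in activated Cre+ cells, each without a member passing. The 14 B cell markers had a median of 0.67 (camera adjusted p = 2.8e-08, and adjusted p = 0.220 with an estimated correlation), for example Cd79b at 1.10 (SE 0.31) and Cd74 at 0.95 (SE 0.31). The 14 myeloid markers had a median of 0.13 (camera adjusted p = 0.0208, and adjusted p = 0.465 with an estimated correlation). The arrays also differed within genotype. The mean level of 29 cell cycle genes was 8.81 on Cre- activated array 3 and 8.48 on Cre+ activated array 3, against 6.72 and 6.71 on the other Cre- and 7.25 and 6.64 on the other Cre+ activated arrays. The mean of the B cell markers was likewise highest on the array numbered 3 of both genotypes, 7.04 and 7.73. Without both of those arrays, an alternative added after seeing the data, 7 of the 24 cytokine genes passed and the cytokine list kept its call (camera adjusted p = 7.0e-15), while the B cell median was 0.67 (camera adjusted p = 1.9e-10). The interferon-stimulated genes then had a median of 0.39 (4 of 29 higher, camera adjusted p = 1.65e-06) against 0.18 with all arrays, and the activation markers 0.18 against 0.10. In that fit the Th1 (median 0.06, camera adjusted p = 0.0778), Th17 (0.150), p53 (0.0643) and myeloid (0.103) lists lost their calls, and the cell cycle list gained one at a median of 0.20 (0.000161, against 0.800 with all arrays). The list calls of that fit used the preset correlation only. The B cell mean on Cre+ array 1, which it kept, was 7.21. The other kept arrays read 5.84 and 6.28 (Cre-) and 6.44 (Cre+ array 2). The cell cycle mean of Cre+ array 1 was also above theirs. That fit therefore kept part of the difference between arrays and cannot separate it from genotype.

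The fit of all 12 arrays shared its estimate of the spread between the groups, and the activated groups spread more, with a median SD over genes of 0.176 and 0.172 against 0.134 and 0.128 at baseline in Cre- and Cre+ cells. In a limma fit of the 6 activated arrays alone, 9 genes passed, all higher in Cre+ cells, with Ctnnd1 (adjusted p = 0.00584), Ccn4 (adjusted p = 0.00793), Il3 (adjusted p = 0.0335) and Trim16 (adjusted p = 0.0376) among them, and 3 of the 33 named genes that had passed kept their calls (Il3, Ctnnd1 and Ccn4). Array weights called 2416 genes, 1204 higher and 1212 lower, sex as a covariate 112, and leaving out Cre- activated arrays 1, 2 or 3 or Cre+ activated array 1 gave 93, 82, 283 and 72.

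Of the genes that passed in each state, 47 were higher in both and 3 were lower in both. Both comparisons share 1 estimate of each gene's spread, so no number expected for independent lists is given. Of the 128 genes that passed at baseline, 122 differed in the same direction after activation, with a median of 0.63 on the log2 scale there against 0.98 at baseline. Of the 169 that passed after activation, 149 had the same direction at baseline. Across all genes, which are not independent replicates, the genotype effects of both states correlated at 0.336.

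**Figure D2:**
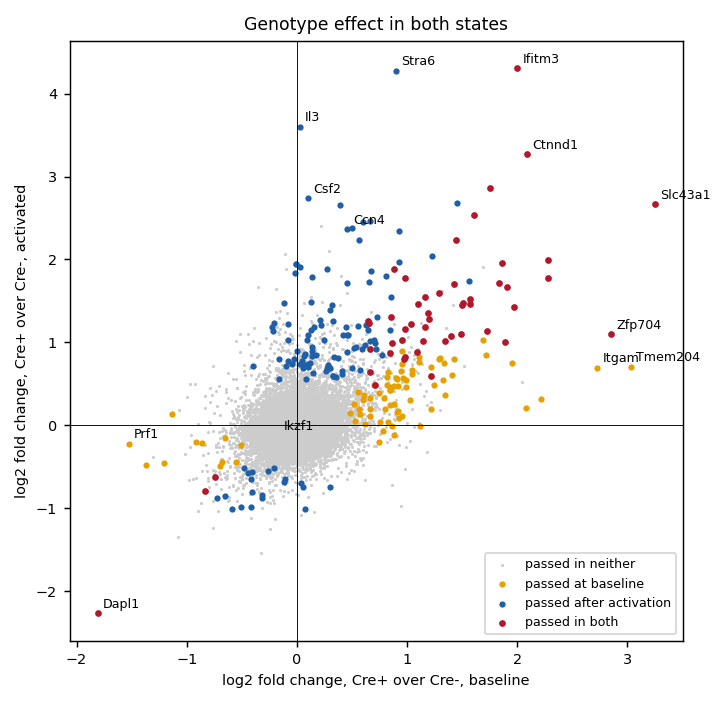
Log2 fold change of Cre+ over Cre- cells at baseline (horizontal) and after activation (vertical), with 1 point per gene and genes linked to sex left out. Colours show in which state a gene passed the limma test, and Ifitm3, Ctnnd1 and Slc43a1 were far from 0 in both states, Il3, Csf2 and Stra6 mainly after activation, and Tmem204 and Itgam mainly at baseline.

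Activation changed Cre- cells broadly. The chemokine gene Ccl22 rose from 3.48 ± 0.49 to 8.83 ± 0.29 (SD, n = 3), Il2 from 2.70 ± 0.13 to 7.93 ± 0.63, and Gzmb, which encodes a cytotoxic granule protease, from 3.67 ± 0.37 to 7.85 ± 0.55. The baseline means of these genes lay below the array medians. Ccl3 rose by 5.10 on the log2 scale, Pros1 by 5.03, the asparagine synthetase gene Asns by 4.10, Irf4 by 3.74 (SE 0.12, limma adjusted p = 1.5e-08) and the cell cycle inhibitor gene Cdkn1a by 3.65. Steep decreases were in Fcmr (-4.48), Igha (-4.45), Klk1 (-4.44), Cd180 (-4.44), Ifi208 (-4.42), Pld4 (-4.27), Jchain (-4.14) and Siglech (-4.14), of which Igha and Jchain encode an immunoglobulin heavy chain and the chain that joins immunoglobulin units in B lineage cells. Which cells of the samples the steep decreases came from was not tested in either genotype. Without Cre- activated array 3 Klk1 read -5.72, Cd180 -5.13 and Pld4 -4.90, and without array 1 or 2 Klk1 read -3.81 or -3.79. In total 4287 genes passed, 2177 higher and 2110 lower, and 1548 changed at least 2-fold. With each array centred on its median the split was 2686 higher and 1696 lower, or 61.3% higher against 50.8%, and with each array set to its 75th percentile it was 2004 higher and 2331 lower.

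Of 18 activation markers, 15 rose in Cre- cells, among them Nr4a3 (3.21), Tnfrsf4 (2.34) and Il2ra (2.34), and the list passed (camera adjusted p = 6.2e-18, and adjusted p = 0.000335 with an estimated correlation). Adjusted over the list alone, 17 rose and 1 fell. Cytokines had 13 of 24 members higher and 1 lower, the same numbers when adjusted over the list alone, with Ifng at 3.48, Lta at 2.36, Tnf at 1.97 and Csf2 at 1.42 (camera adjusted p = 5.1e-10, and adjusted p = 0.0101 with an estimated correlation). The IL-2 and STAT5 pathway had 9 of 13 members higher, also when adjusted over the list alone, including Cish (2.61) and Stat5a (1.57). Glycolysis genes had 11 of 14 higher, with Hk2 at 3.17, Tpi1 at 2.48 and the lactate transporter gene Slc16a3 at 1.94. Th2 genes had 7 of 12 higher and 1 lower, with Ccr8 at 2.78, Il13 at 2.62 and Il4 at 1.76. These last 3 lists passed at camera adjusted p = 6.9e-11, 1.7e-09 and 6.6e-05, and at adjusted p = 0.0140 each with an estimated correlation.

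All 14 ribosome biogenesis genes rose in Cre- cells, for example Gnl3 (1.62) and Polr1b (1.53), and 10 of 15 cholesterol synthesis genes rose, for example Cyp51 (1.74) and Sqle (1.49). The lists passed at camera adjusted p = 3.1e-11 and 1.5e-07, and each had an adjusted p = 0.179 with an estimated correlation. Of 29 cell cycle genes, 5 rose, among them Ccnd2 (0.73) and the replication licensing genes Mcm2 (1.46), Mcm5 (1.66) and Mcm6 (1.35). That list's call (camera adjusted p = 0.000969) was not held with an estimated correlation (adjusted p = 0.621), nor without Cre- activated array 3 (camera adjusted p = 0.405). Of 12 unfolded protein response genes, 5 rose, Xbp1 by 1.28 and Atf4 by 0.92 among them, and 2 fell (camera adjusted p = 0.0271, and adjusted p = 0.179 with an estimated correlation). The 11 p53 targets had 5 members higher, with Sesn2 at 1.70 (camera adjusted p = 0.00114, and adjusted p = 0.0918 with an estimated correlation). The 15 Th1 genes had 6 higher, Tbx21 (2.34) and Il12rb1 (2.50) among them, and 3 lower (camera adjusted p = 0.00717, and adjusted p = 0.191 with an estimated correlation).

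Lists that fell in Cre- cells included markers of other cell types. Of 14 B cell markers, 13 fell, for example Cr2 by 4.04, Cd79b by 2.91 and H2-Eb1 by 2.05, with a list median of -2.33 (camera adjusted p = 2.0e-14, and adjusted p = 0.104 with an estimated correlation). Of 14 myeloid markers, 12 fell, for example Itgax by 2.86 and Fcer1g by 2.17, with a median of -1.68 (camera adjusted p = 2.2e-13, and adjusted p = 0.0392 with an estimated correlation). Of 8 NK cell markers, 4 fell (camera adjusted p = 0.0190, and adjusted p = 0.149 with an estimated correlation). Interferon-stimulated genes split, with 13 of 29 lower, such as Oas2 (-2.60) and Ddx58 (-2.11), and 5 higher, such as Gbp2 (3.19) and Irgm1 (1.40), and the list passed downward (camera adjusted p = 0.00133, and adjusted p = 0.299 with an estimated correlation). Chemokine receptors and integrins had 10 of 20 members lower, Itga4 by 2.01, and 2 higher (camera adjusted p = 0.00013, and adjusted p = 0.179 with an estimated correlation).

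Of 13 naive and quiescence genes, 5 fell, such as the IL-7 receptor gene Il7r (-2.44), Foxo1 (-1.15) and Btg2 (-1.85), and Bach2 rose by 0.55 (camera adjusted p = 0.0138, and adjusted p = 0.536 with an estimated correlation). Of 16 T cell receptor signalling genes, 5 fell, including Themis (-1.63) and Cd3g (-0.64), and 10 fell when adjusted over the list alone (camera adjusted p = 0.000724, and adjusted p = 0.421 with an estimated correlation). The 8 immature thymocyte genes had 3 lower, Dntt by 2.02 (camera adjusted p = 0.00912, and adjusted p = 0.0876 with an estimated correlation). Outside these lists, Dtx1, a regulator in the Notch pathway, fell by 3.55, and Ikzf1 fell by 0.42 (SE 0.13, limma adjusted p = 0.0458), a call lost in 14 alternative settings.

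In Cre+ cells, activation raised and lowered many of the same genes. Il2 rose from 2.83 ± 0.11 to 9.42 ± 0.47 (SD, n = 3), Ccl22 from 3.81 ± 0.18 to 9.77 ± 0.74, Ifng from 3.65 ± 0.21 to 8.99 ± 0.22 and Il3 from 2.76 ± 0.32 to 8.03 ± 0.46, all from baseline means below the array medians. Ccl3 rose by 5.62 on the log2 scale, Ccl1 by 5.07, Crabp2, which encodes a retinoic acid binding protein, by 4.89, and Gzmb by 4.60. Klk1 fell by 4.80, Ifi208 by 4.28, Itgam by 4.27, Pld4 by 4.26, Siglech by 3.94, Jchain by 3.93, Fcmr by 3.92 and Cd180 by 3.86. Without Cre+ activated array 3 Klk1 read -5.92, Pld4 -4.97 and Cd180 -4.65, without activated array 2 Klk1 read -4.13, and without Cre+ baseline array 3 Siglech read -3.35 and Jchain -3.22. In total 4795 genes passed, 2346 higher and 2449 lower, and 1683 changed at least 2-fold. Of the genes that passed in each genotype, 1752 were higher in both and 1635 lower in both. Across genes, the activation effects correlated at 0.890.

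The lists moved in Cre+ cells as follows. Activation markers had 16 of 18 members higher, with Nr4a3 at 2.96 and Irf4 at 2.90 (camera adjusted p = 5.4e-17, and adjusted p = 0.000409 with an estimated correlation). Cytokines had 16 of 24 higher and none lower, with Csf2 at 4.06, Il13 at 3.31 and Lta at 2.67 (camera adjusted p = 6.8e-15, and adjusted p = 0.00220 with an estimated correlation). The IL-2 and STAT5 pathway (10 of 13 higher, Cish at 2.38), glycolysis (11 of 14 higher and 1 lower, Hk2 at 3.57) and Th2 genes (6 of 12 higher and 1 lower) passed with adjusted p = 0.0191 each with an estimated correlation. The p53 targets had 7 of 11 members higher, Cdkn1a by 4.54 and Sesn2 by 2.20 (camera adjusted p = 2.4e-05, and adjusted p = 0.0365 with an estimated correlation). All 14 ribosome biogenesis genes rose and 9 of 15 cholesterol synthesis genes rose, and both lists had an adjusted p = 0.170 with an estimated correlation. Th1 genes had 8 of 15 higher and 2 lower (camera adjusted p = 0.000166, and adjusted p = 0.0855 with an estimated correlation), and the unfolded protein response had 6 of 12 higher and 2 lower (camera adjusted p = 0.00322, and adjusted p = 0.0853 with an estimated correlation).

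Inhibitory receptors and anergy genes had 6 of 14 members higher in Cre+ cells, such as Lag3 (2.42) and Egr2 (1.47), and 2 lower (camera adjusted p = 0.0280, and adjusted p = 0.355 with an estimated correlation). Cell cycle genes had 5 of 29 higher, Mcm5 by 1.89 (camera adjusted p = 0.000614, and adjusted p = 0.533 with an estimated correlation), and without Cre+ activated array 3 the list did not pass (camera adjusted p = 0.0768), while without the arrays numbered 3 of both genotypes it passed (12 higher and 3 lower, camera adjusted p = 0.00568). B cell markers fell in 11 of 14 members, Cr2 by 3.47 and Cd79a by 3.21 (camera adjusted p = 6.2e-08, and adjusted p = 0.223 with an estimated correlation), and myeloid markers in 12 of 14 (camera adjusted p = 3.8e-10, and adjusted p = 0.0679 with an estimated correlation). Interferon-stimulated genes had 17 of 29 lower and 5 higher (camera adjusted p = 0.000524), T cell receptor signalling 8 of 16 lower (0.000166), chemokine receptors and integrins 12 of 20 lower and 2 higher (0.000735), naive and quiescence genes 5 of 13 lower and 1 higher (0.00719). With an estimated correlation these lists had adjusted p = 0.248, 0.355, 0.248 and 0.458. Immature thymocyte genes had 3 of 8 lower, Dntt by 2.83 (camera adjusted p = 0.00673, and adjusted p = 0.0679 with an estimated correlation), and gamma delta and innate-like T cell markers 2 of 4 lower, Sox13 by 0.50 among them (camera adjusted p = 0.0118, and adjusted p = 0.0853 with an estimated correlation). Array weights called 8292 genes in this comparison, and 3148 and 3175 passed without Cre+ activated arrays 1 and 3. Centring each array on its median gave 2517 higher and 2098 lower.

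The last comparison tested the difference of the activation responses, the change in Cre+ cells minus the change in Cre- cells. Il3 rose by 1.70 in Cre- and by 5.27 in Cre+ cells, a difference of 3.57 (SE 0.36, limma adjusted p = 0.00556). Ccn4, which encodes a secreted matricellular protein, rose by 0.49 in Cre- and by 2.40 in Cre+ cells, a difference of 1.91 (SE 0.18, limma adjusted p = 0.00556). These were the 2 genes that passed, and 1089 genes had an unadjusted p under 0.05. Ifng (1.86, SE 0.28, limma adjusted p = 0.0881), Csf2 (2.64, SE 0.47, limma adjusted p = 0.221), Ier3 (1.67) and Prf1 (1.31) had differences above 0 that did not pass, Il2 rose by 5.22 in Cre- and by 6.59 in Cre+ cells without the difference passing (limma adjusted p = 0.739), and Itgam (-2.03), Irf4 (-0.85) and Serpinb6b (-0.78) had differences below 0 that did not pass.

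As a list, the cytokines responded more in Cre+ cells, with a median difference of 0.39 (camera adjusted p = 6.3e-10, and adjusted p = 0.0178 with an estimated correlation) and 5 of 24 members passing when adjusted over the list alone. Cytotoxic genes had a median difference of 0.43 (camera adjusted p = 0.000597, and adjusted p = 0.0458 with an estimated correlation), with 1 member higher and 1 lower when adjusted over the list alone. Among the 5 of its genes with a mean of at least 6 this list lost its call, with no evidence of a shift either way (camera adjusted p = 0.956). B cell markers had a median difference of 0.88 (camera adjusted p = 1.5e-10), immediate early and stress genes 0.28 (0.000597), Th1 genes 0.41 (0.00823) and p53 targets 0.12 (0.0275), and each had an adjusted p = 0.269 with an estimated correlation. Follicular helper genes (0.30, camera adjusted p = 0.0174) and Th17 genes (0.18, camera adjusted p = 0.0324) had an adjusted p = 0.191 with an estimated correlation. In the fit without the activated arrays numbered 3, Th1 (camera adjusted p = 0.0581) and Th17 genes (0.0648) lost their calls. Cell cycle (camera adjusted p = 0.00073) and ribosome biogenesis genes (0.0313) then passed upward, and regulatory T cell genes (0.0338) downward. Without Cre- activated array 3, Cre+ activated array 2 or Cre+ activated array 3, 8, 25 and 5 genes passed, and Il3 and Ccn4 passed in each of these fits. Array weights called 143 genes, the replicate number as a block 5, quantile normalization 4, sex as a covariate 4 and the fit without the activated arrays numbered 3 called 11, while the filters on the mean, which remove Il3 and Ccn4, left 0 genes past the limma test (376 and 246 at an unadjusted p under 0.05).

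**Figure D3:**
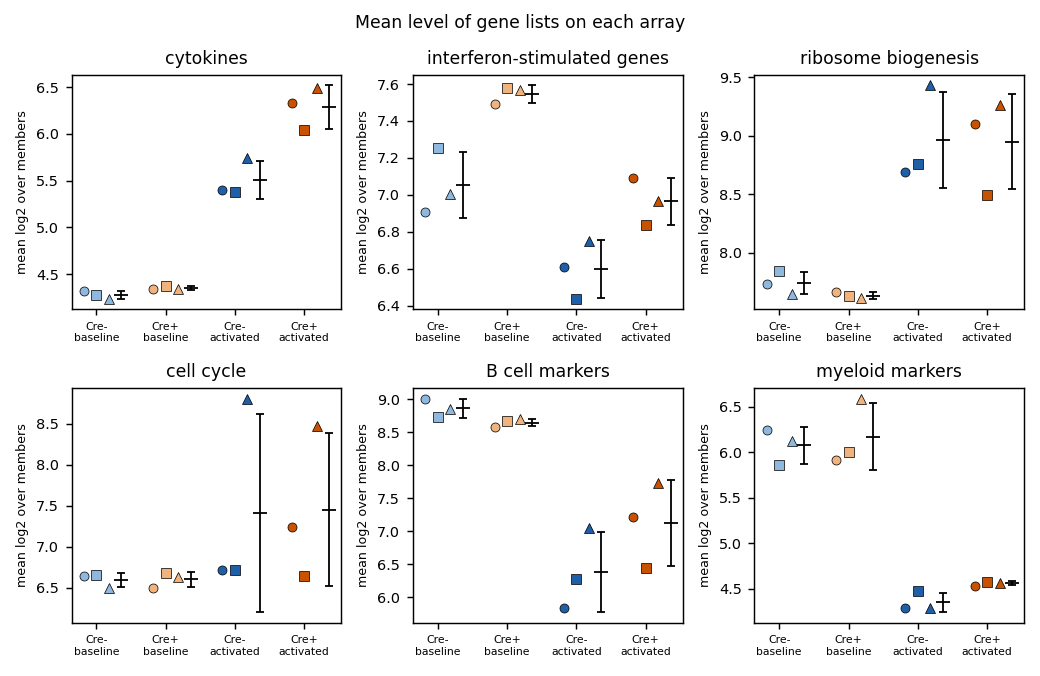
Mean log2 expression of 6 gene lists on each of the 12 arrays. Symbols are the arrays numbered 1 (circle), 2 (square) and 3 (triangle), bars are the mean and SD of 3 arrays, and cytokine genes were highest on the activated Cre+ arrays, and the cell cycle list reached 8.81 and 8.48 on the activated arrays numbered 3.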

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

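All tests of this part were planned except the tests of immunoglobulin segments, of CD8 T cell markers and of calls by their Cre- level, and the fits with sex as a covariate or without the third activated arrays, which were chosen after the result was seen.

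Il3 responded more to activation in Cre+ than in Cre- cells by 3.57 on the log2 scale, and Ccn4 by 1.91, by a direct test of the difference. Gene lists whose responses differed by the same test, at the preset correlation, were the cytokines (camera adjusted p = 6.3e-10), B cell markers (1.5e-10), cytotoxic genes (0.000597), immediate early and stress genes (0.000597), Th1 genes (0.00823), follicular helper genes (0.0174), p53 targets (0.0275) and Th17 genes (0.0324). Of these, the cytokines (adjusted p = 0.0178) and the cytotoxic genes (adjusted p = 0.0458) kept the call with an estimated correlation. Some of the lists share members, so their calls are not independent. Ifng is in the cytokine and Th1 lists, and Il21 in the cytokine, Th17 and follicular helper lists. Of 100 relabellings of genotype within each state, 24 gave at least the 2 genes of the real one, and the highest of the others gave 1864, so chance is not excluded for that count. Outside the genes tested, 8 probe sets with no listed gene were higher in Cre+ cells at baseline and 9 after activation.

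More genes were higher than lower in Cre+ cells in both states. A scaling difference between arrays is not favoured, since the share of calls that were higher was at least 83.67% under 3 rescalings, and a floor that lets dim genes only rise is not favoured, since among calls whose Cre- mean in the same state was at least 6, 26 of 32 at baseline and 49 of 60 after activation were higher (lower 95% exact limits 63.56% and 69.56%, taking genes as independent). With sex as a covariate the share was at least 90.59%. With array weights after activation, however, 49.83% of 2416 calls were higher, so the asymmetry in activated cells depends on how the arrays are weighted. Whether release of genes that Ikaros represses could account for the pattern was not tested.

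The activated arrays differed within genotype, since Cre- array 3 correlated at 0.972 and 0.976 with the other 2, which correlated at 0.994 with each other, while in Cre+ cells arrays 2 and 3 were the farthest pair at 0.976. Fewer B or myeloid cells on the arrays numbered 3 is not favoured, since the B cell medians lay above the others by 0.98 in Cre- and 0.815 in Cre+ cells and the myeloid medians differed by 0.054 and -0.0845, but the 2 CD8 T cell markers had medians of -0.891 and -0.501, so fewer CD8 T cells stays open. The 18 regulatory T cell genes were also lower on those arrays, with medians of -0.863 and -0.68. The fall was therefore not particular to the CD8 T cell markers. A candidate explanation is T cells further along the activation response. The cell cycle median of those arrays was higher by 2.09 in Cre- and by 1.48 in Cre+ cells. Ribosome biogenesis genes were also higher there (0.684 and 0.445), and naive and quiescence genes were lower (-0.728 and -0.37). Activation markers (0.0842 and -0.0584) and the IL-2 and STAT5 pathway (-0.282 and -0.268) did not rise, so this explanation stays an open hypothesis. Of the 10 splits of the 6 activated arrays, 2 gave at least the 169 genes of the real one. The split that put Cre- arrays 1 and 2 with Cre+ array 2 gave 3915 genes, which points to a structure of the samples that genotype does not follow, and 10 splits cannot give a share under 0.05.

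B cell and myeloid lists passed downward after activation in both genotypes, and with an estimated correlation the B cell list had adjusted p = 0.104 in Cre- and 0.223 in Cre+ cells and the myeloid list 0.0392 and 0.0679. A lower share of other cells in the activated cultures may account for this. The 185 immunoglobulin variable segments had medians of -1.85 in Cre- and -1.33 in Cre+ cells. By limma 143 and 106 of them were lower and 0 higher. Being B lineage transcripts themselves, they cannot tell fewer B cells from lower expression within B cells. They do not bear on the myeloid list. The B cell list shares Blk with the gamma delta list, and activated or antigen-presenting cells of other kinds express its class II genes. In Cre- cells Cd74 read 11.07 at baseline and 8.94 after activation, and Cd79a read 9.65 and 5.64. Lower expression within such cells was not tested and stays open.

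For the other comparisons, 10 splits are too few for a share under 0.05. The real split was 1 of 10 with as many genes at baseline (128, highest other 0), for activation in Cre- cells (4287, highest other 0) and for activation in Cre+ cells (4795, highest other 0).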

How the results depend on the processing

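The fits with sex as a covariate and without the third activated arrays were chosen after the result was seen. For genes differing at baseline (128), array weights gave 321, means of at least 5 and 6 gave 83 and 43, a 2-fold minimum 61, the fit without the third activated arrays 266, sex 85, only the arrays compared 251, and leaving out 1 array 50 to 199. After activation (169), array weights gave 2416, a mean of at least 6 gave 79, a 2-fold minimum 95, sex 112, only the arrays compared 9, and leaving out 1 array 72 to 283. A 2-fold minimum gave 1548 for activation in Cre- cells and 1683 in Cre+ cells, where array weights gave 8292 and leaving out 1 array 3148 to 5922. For the difference of responses (2), the replicate block gave 5, array weights 143, means of at least 5 and 6 gave 0 by limma (376 and 246 at an unadjusted p under 0.05), quantile normalization 4, the fit without the third activated arrays 11, sex 4, and leaving out 1 array 2 to 25. Filters tested fewer genes, 9444 and 7192, and a left-out array leaves fewer samples. Otherwise the cause was not tested.

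The cytotoxic list in the difference of responses lost its call with means of at least 6 (camera adjusted p = 0.956, 5 genes tested). Its estimate changed sign there without evidence of a shift either way. Of 63 list calls, 47 were lost with an estimated correlation, 12 with array weights and 21 with means of at least 6, this cytotoxic call not counted. Some lists that lost their call with an estimated correlation had one below the preset 0.01. A higher correlation between members therefore does not account for every loss. Of the named genes that passed, 16 of 29 at baseline, 3 of 33 after activation, 101 of 109 and 101 of 113 for activation in Cre- and Cre+ cells, and 2 of 2 for the difference of responses passed in every setting that tested them. The replicate block gave 127, 189, 4692, 5082 and 5 genes. Of 18 pairs of arrays with the same number, 5 had residuals that correlated above 0.1 (range -0.0948 to 0.728). Of 12 arrays, 7 matched best with their own number. Within a state, activated Cre- and Cre+ arrays 2 and 3 correlated at 0.571 and 0.728 and baseline arrays 2 and 3 at 0.137 and 0.149. The arrays numbered 1 gave -0.0455 activated and -0.0254 at baseline. The model without pairs was chosen before the data were examined, and these correlations do not settle whether the numbers mark pairs. In Cre- cells Xist read 2.83 on baseline array 3 and 9.9 on activated array 3. In Cre+ cells it read 10.35 on baseline array 1 and 2.87 on activated array 1. Eif2s3y moved the opposite way in both cases. For these arrays the numbers therefore did not mark 1 animal across states. Pairs of another kind stay open. The mean of several probe sets per gene was not run, since each gene had 1. Il3 and Ccn4 had means under 5 over all arrays, so the filters on dim signal did not test them.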

Other observations

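The choice of genes followed across states here was made after the result was seen. Genes that were higher in resting Cre+ cells did not share 1 fate on activation. In Cre+ cells Tmem204 fell by 2.52, Slc15a1 by 2.31, Adgrg3 by 2.04, Cd163l1 by 1.82 and Zfp704 by 1.52. Ctnnd1 rose by 1.00, and Ifitm3 rose by 1.13 in Cre+ cells and fell by 1.19 in Cre- cells. Slc43a1 (0.21), Eng (-0.48) and Trim16 (-0.27) did not pass in Cre+ cells. Zfp704 was still higher in activated Cre+ cells by 1.10 (limma adjusted p = 0.0118). The responses of Tmem204 (-2.32), Slc15a1 (-1.90), Cd163l1 (-1.87) and Zfp704 (-1.75) had differences between genotypes with a limma adjusted p = 0.0525 each, those of Ifitm3 (2.31) and Adgrg3 (-1.20) at 0.325 each and that of Ctnnd1 (1.18) at 0.328, so none of these differences passed.

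Several lists passed in no comparison of the fit of all arrays. The Notch pathway had medians of 0.08 at baseline and 0.06 after activation between genotypes, with 1 of 12 members higher and 2 lower on activation in each genotype. The NuRD and Sin3 complexes, with which Ikaros is known to associate, had medians of -0.03 and -0.02 between genotypes, with 3 of 15 members higher and 2 lower on activation in Cre- cells and 4 higher and 2 lower in Cre+ cells. Markers of CD8 T cells (2 measured) had medians of 0.21 and 0.30 between genotypes, erythroid markers (6 measured) 0.03 and -0.08, platelet markers (7 measured) 0.02 and -0.07, and the 4 measured genes linked to sex -1.52 and 1.39, with no member of these passing between genotypes. The Ikaros family passed in no comparison as a list with all arrays, and in the fit without the third activated arrays, chosen after seeing the data, it passed upward at baseline (camera adjusted p = 0.00278, 2 of 5 members higher).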
